A study of Mus musculus with 24 samples.

How the data were processed

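RNA of snap-frozen liver from 24 samples, 4 in each of 6 groups of strain and diet, was purified on RNeasy columns and labelled with Cy3 from 0.5 ug by the authors, per the labels' protocols, and hybridised to mouse arrays on 3 slides of 8 arrays. Both diets were supplemented with iron, and the time of day of collection is not in the labels. Per the file headers, the intensity of each spot was made by the authors with Agilent Feature Extraction 10.7, which subtracted background and removed spatial and multiplicative trends within each array without scaling between arrays. The other values per the file headers are flags of 0 or 1 for spots well above background, saturated or outlying. The deposited table of the authors' normalized intensities equalled the processed signal times 1 constant per array, and 0 of its columns remained without a sample.

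Spots with an outlier flag were left out (3332 over all arrays), replicate spots were averaged, and log2 processed signals were scaled by subtracting the array's 75th percentile. Of 55681 distinct gene probes, 33250 were given a gene name, 26762 through a RefSeq accession, 3806 through the symbol, 638 through a synonym and 2044 by keeping the name in the file. The 22431 others were left out of the comparisons and tested as an alternative. A probe was tested if it was well above background on all 4 arrays of at least 1 group (28155 probes), and each gene was represented by its brightest probe, which gave 15705 genes. No genome came with the series, so positions are those printed in the array files and probes were not realigned.

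One model with a mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (version 1.17.8 of data.table read the files). Its moderated tests, 2-sided, compared the diets within each strain, the diet effects between strains and the strains on the control diet, with an F test of the diet effects over the strains, and Benjamini-Hochberg adjusted p over all genes of each comparison was held to 0.05. Camera tested 32 gene lists with a preset correlation of 0.01, adjusted over the lists of each comparison, and camera with an estimated correlation and fry, which tests the genes of a list alone, were run beside it. The lists held 595 members, 549 of them tested. Comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The number of arrays limits the precision of every value. Tested on simulated data with equal spread, the fit recovered between 68% and 76% of genes changed 2-fold.

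Named genes are those of a fixed panel of 52, the 6 largest rises and 6 largest falls past the threshold in each strain and alike in all strains, the 4 largest differences in each direction between diet effects, the 3 largest between strains on the control diet, and up to 2 list members with the lowest adjusted p. Ranked genes had to be above background on at least 3 arrays in each group, and groups could not overlap for the largest changes in 1 strain and between strains on the control diet. For differences between diet effects overlap was allowed, although the plan can be read as excluding it. A gene named in 1 comparison is also given in others, as Dbp in A/J; Ly6a and Pax2 in WSB/EiJ and Oas1a in C3H/HeJ are such values, chosen after they were seen.

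Alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the deposited table, no background filter, probes above background on all arrays, the mean of a gene's probes, slide or replicate number as a block, a trended robust prior, array weights, only the compared groups in the fit, an adjusted p of 0.01, a log2 change of at least 1, and each array left out in turn. Scaling on the E1A spike-in probes, inclusion of unnamed probes and 1 array fewer in each group (the one with the lowest mean correlation with its own group) were chosen after the data were seen.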

Results

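Liver RNA of male mice of the inbred strains A/J, C3H/HeJ and WSB/EiJ was measured on 24 single-colour expression arrays, 4 per strain and diet. The deficient diet lacked choline and folic acid and was low in methionine (0.17%) for 12 weeks, and control mice received the same diet with methionine (0.4%), choline bitartrate (0.3%) and folic acid (2 mg/kg). Mice were 20 weeks old. The series title asks how the strains differ in liver injury on such a diet and in lipid metabolism genes. Between 44.4% and 56.0% of gene spots were well above background on each array, saturated gene spots numbered 0, and 15705 genes were tested. The labels name replicates as separate samples of randomly allocated mice but do not say that each array is a separate animal, so p-values measure the spread between these samples. Values are log2 fold changes, deficient over control, with ± the standard error of limma (n = 4 arrays per group). An array left out is named by its diet and replicate number. Values noted with fewer than 4 arrays of a group above background rest partly on signals near background, so their size is uncertain. List members counted neither as rising nor as falling did not pass, and the adjusted p of a list is camera's. A fold given as at least a value is a lower bound: the mean of the brighter group over the mean of the dimmer one, with each dim array at the higher of the gene's own signal and the lowest signal among probes well above background. Gene positions are those of the probe in mouse build NCBI37 (mm9) as the array files give them.

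In A/J livers on the deficient diet, 7 of 18 lipid droplet and PPAR-gamma targets, 9 of 21 macrophage and monocyte markers and 9 of 23 cell cycle genes rose, while 9 of 23 hepatocyte function genes and 6 of 20 drug-metabolising cytochromes fell. Apoa4 (chromosome 9, 46049661 to 46050404), an apolipoprotein of triglyceride-rich particles, rose 12.4-fold (3.63 ± 0.25), Vnn1, the pantetheinase vanin, rose 16.7-fold (4.06 ± 0.33) and Cidec, a lipid droplet protein, rose 9.21-fold (3.20 ± 0.55). Trem2, a receptor of lipid-laden macrophages, rose 23.1-fold (4.53 ± 0.48, 3 of 4 control arrays above background), and Gpnmb, not well above background on the control diet, rose at least 4.35-fold (adjusted p = 2.8e-04). Rad51b, a recombination factor, rose by 4.00 ± 0.30, Nrg1, a growth factor, by 4.2 ± 0.39 (3 of 4 control arrays above background) and Lcn2, an acute phase protein, by 3.21 ± 0.48. Among the genes that fell were Slc13a2, a dicarboxylate transporter (-3.22 ± 0.48), Ly6a (-3.16 ± 0.50) and Serpina4-ps1 (-3.45 ± 0.79). Gnmt, the glycine methyltransferase that uses S-adenosylmethionine, was also lower (-1.19 ± 0.30). Leaving out 1 array ended the call of Gnmt (without deficient 1 or 3, -1.13 to -1.04, adjusted p = 0.0503 to 0.0629).

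Limma called 1612 of 15705 genes in A/J, 885 higher and 727 lower on the deficient diet, and 861 when only the groups compared shared the spread. The count was 778 to 1035 without deficient 1 or 3 or control 1 or 3, and 4625 with 1 array fewer in each group. On arrays simulated with each group's own spread and 50 genes changed at each of 4 folds, 29.9% of calls were unchanged genes (8.45% with only the A/J groups fitted). This share depends on how many genes change. The share of calls that were higher was 54.9%, 39.4% with 1 array fewer in each group, 42.5% with array weights, 48.0% with only probes above background on all arrays and 95.6% with spike-in scaling. With slide as a fixed block 2164 genes were called in A/J, and 1896 as a random one; within slides 1, 2 and 3, 16, 15 and 16 of the 16 called lists kept the sign of their median (17 lists called with the block). Calling the lists on these same arrays largely fixes such agreement. On the mean of 6583 genes called alike in C3H/HeJ and WSB/EiJ, A/J control 4 stood at -1.90 and deficient 4 at -1.94, so these arrays did not separate by diet there.

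Of 18 lipid droplet and PPAR-gamma targets, 7 rose and 0 fell (8 and 0 adjusted over the list alone), median 0.60, adjusted p = 6.4e-09, adjusted p = 0.00795 with an estimated correlation. Pparg, the adipogenic receptor, was among them (1.24 ± 0.22), as were Cd36, a fatty acid transporter (2.45 ± 0.25), and Mogat1 (2.92 ± 0.48). Of 26 fatty acid oxidation and ketogenesis genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), median 0.21, adjusted p = 1.1e-05, adjusted p = 0.465 with an estimated correlation. Fgf21, a hormone of the starved liver, rose by 2.40 ± 0.47. Of 22 fatty acid and triglyceride synthesis genes, 1 rose and 4 fell (3 and 5 adjusted over the list alone), median -0.18, adjusted p = 0.577. Fasn, fatty acid synthase, fell (-1.07 ± 0.33). Of 21 lipoprotein assembly and clearance genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), median -0.24 (mean 0.051, camera direction down), adjusted p = 0.683. Apob was at -0.14 ± 0.14, opposite in sign with quantile normalization, normexp correction and spike-in scaling, adjusted p = 0.556. Of 23 cholesterol synthesis genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone), median -0.44, adjusted p = 7.4e-04, adjusted p = 0.580 with an estimated correlation. Of 19 bile acid synthesis and transport genes, 1 rose and 1 fell (1 and 7 adjusted over the list alone), median -0.32, adjusted p = 0.0544. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.50 ± 0.48, adjusted p = 0.0502. Of 35 methionine, folate and choline metabolism genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone), median -0.18, adjusted p = 0.211. Bhmt (-0.84 ± 0.22) and Cbs (-0.79 ± 0.16) fell and Mthfd2, a mitochondrial folate enzyme, rose (1.24 ± 0.30, 3 of 4 control arrays above background). Of 13 DNA methylation enzymes, 0 rose and 2 fell (0 and 2 adjusted over the list alone), median 0.030 (mean -0.062, camera direction down), adjusted p = 0.983. Dnmt3b, a de novo DNA methyltransferase, fell (-0.89 ± 0.19). Without 1 array the call was lost for Bhmt (without control 1 or deficient 2 or 3, -0.80 to -0.74, adjusted p = 0.0543 to 0.0588) and Fasn (without control 1, 2 or 3 or deficient 1, 2 or 3, -1.19 to -0.92, adjusted p = 0.0505 to 0.149). A single array decided the call of Mthfd2 (without deficient 3, 0.99, adjusted p = 0.0571). Settings that ended calls included no background filter (Fasn), normexp correction (Mthfd2), only the compared groups fitted (Dnmt3b and Fasn), unnamed probes included (Fasn) and spike-in scaling (Bhmt, Dnmt3b and Fasn).

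Of 27 extracellular matrix and stellate cell activation genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone), median 0.68, adjusted p = 1.3e-06, adjusted p = 0.478 with an estimated correlation. Timp1, an inhibitor of matrix proteases, rose (3.44 ± 0.58, 2 of 4 control arrays above background), and Col1a1 was at 1.85 ± 0.60, adjusted p = 0.0553. Of 21 macrophage and monocyte markers, 9 rose and 0 fell (14 and 0 adjusted over the list alone), median 0.95, adjusted p = 5.1e-09, adjusted p = 0.268 with an estimated correlation. Cd68, a macrophage lysosomal protein, rose by 1.17 ± 0.22. Of 16 chemokines and inflammatory mediators, 9 rose and 0 fell (13 and 0 adjusted over the list alone), median 1.38, adjusted p = 5.1e-09, adjusted p = 0.268 with an estimated correlation. Ccl2, a monocyte attractant, rose by 3.05 ± 0.62. Of 15 lymphocyte markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone), median 0.31, adjusted p = 0.412. Of 6 neutrophil markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone), median -0.16, adjusted p = 0.324. Of 13 biliary and progenitor markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone), median -0.029 (mean 0.022, camera direction up), adjusted p = 0.737. Of 13 endothelial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone), median 0.034, adjusted p = 0.136. Of 5 mesothelial markers, 1 (Krt8, a liver keratin, 0.51 ± 0.15) rose and 0 fell (1 and 0 adjusted over the list alone), median 0.51, adjusted p = 0.110. Of 23 cell cycle genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone), median 0.78, adjusted p = 6.4e-09, adjusted p = 0.268 with an estimated correlation. Ccnd1, cyclin D1, rose (2.02 ± 0.22), as did Mki67, a marker of dividing cells (0.89 ± 0.28). Leaving out 1 array ended the call of Krt8 (without control 1, 2 or 3 or deficient 1 or 3, 0.41 to 0.52, adjusted p = 0.0673 to 0.144) and Mki67 (without control 1, 2 or 3 or deficient 1, 2 or 3, 0.62 to 0.94, adjusted p = 0.0717 to 0.165). Calls were lost with, among others, the mean of all probes of a gene (Krt8 and Mki67), median centring (Mki67), no background filter (Krt8 and Mki67), only the compared groups fitted (Krt8 and Mki67), unnamed probes included (Mki67) and spike-in scaling (extracellular matrix and stellate cell activation list).

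Of 16 p53 and DNA damage response genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), median 0.069, adjusted p = 0.0180, adjusted p = 0.465 with an estimated correlation. Of 20 unfolded protein and amino acid stress response genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), median -0.16 (mean 0.13, camera direction down), adjusted p = 0.975. Asns, asparagine synthetase, rose (1.81 ± 0.48). Of 23 oxidative stress and glutathione genes, 4 rose and 4 fell (5 and 7 adjusted over the list alone), median -0.19, adjusted p = 0.355. Of 20 drug-metabolising cytochromes, 0 rose and 6 fell (0 and 7 adjusted over the list alone), median -0.55, adjusted p = 4.2e-04, adjusted p = 0.543 with an estimated correlation. Cyp2c29 fell (-1.48 ± 0.24). Of 14 male-biased liver genes, 1 rose and 3 fell (1 and 8 adjusted over the list alone), median -0.57, adjusted p = 0.00732, adjusted p = 0.497 with an estimated correlation. Hsd3b5 (-1.51 ± 0.41) and Elovl3 (-2.70 ± 0.55) fell. Of 10 female-biased liver genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), median 1.42, adjusted p = 0.00510, adjusted p = 0.465 with an estimated correlation. Of 23 hepatocyte function genes, 0 rose and 9 fell (0 and 11 adjusted over the list alone), median -0.62, adjusted p = 1.1e-06, adjusted p = 0.488 with an estimated correlation. F7, coagulation factor VII, fell (-0.78 ± 0.15), and albumin (Alb) was at -0.41 ± 0.15, adjusted p = 0.0928. Of 17 acute phase response genes, 1 rose and 4 fell (2 and 7 adjusted over the list alone), median -0.19 (mean 0.046, camera direction down), adjusted p = 0.305. Without 1 array the call was lost for Asns (without control 1, 2 or 3 or deficient 3, 1.45 to 1.74, adjusted p = 0.0517 to 0.0910) and Hsd3b5 (without control 2 or deficient 3, -1.39 to -1.24, adjusted p = 0.0634 to 0.0927). A single array decided the call of the p53 and DNA damage response list (without deficient 3, 0.11, adjusted p = 0.0518). Calls ended with, among others, 1 array fewer in each group (female-biased liver genes list), normexp correction (Asns), only probes above background on all arrays (female-biased liver genes list), only the compared groups fitted (Asns), quantile normalization (p53 and DNA damage response list) and spike-in scaling (female-biased liver genes list and p53 and DNA damage response list).

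Of 14 fetal and tumour-associated liver genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), median 0.60, adjusted p = 7.3e-05, adjusted p = 0.465 with an estimated correlation. Ly6d rose (5.22 ± 0.83), and Afp, alpha-fetoprotein, was at 0.40 ± 0.27, adjusted p = 0.366. Of 18 circadian clock genes, 5 rose and 2 fell (6 and 4 adjusted over the list alone), median 0.42, adjusted p = 0.0544. Dbp rose (2.49 ± 0.58) and Arntl fell (-1.77 ± 0.30). Of 20 interferon response genes, 4 rose and 0 fell (5 and 1 adjusted over the list alone), median 0.20, adjusted p = 0.0118, adjusted p = 0.580 with an estimated correlation. Oas1a rose (1.14 ± 0.22). Of 18 iron handling genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), median -0.18, adjusted p = 0.371. Of 10 pancreas markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone), median 1.57, adjusted p = 0.00852, adjusted p = 0.580 with an estimated correlation. Of 5 adipose tissue markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone), median -0.12 (mean -0.0055, camera direction up), adjusted p = 0.983. Of 5 blood cell (erythroid) markers, 0 rose and 1 fell (0 and 4 adjusted over the list alone), median -0.78, adjusted p = 0.00851, adjusted p = 0.465 with an estimated correlation. Hba-a2, an alpha globin, fell (-0.78 ± 0.22). Leaving out 1 array ended the call of Hba-a2 (without control 1 or 4 or deficient 1 or 3, -0.80 to -0.61, adjusted p = 0.0557 to 0.106), the interferon list (without control 3 or deficient 1, 0.071 to 0.094, adjusted p = 0.110 to 0.210) and the pancreas list (without deficient 1, 0.14, adjusted p = 0.456). Settings that ended calls included 1 array fewer in each group (blood cell (erythroid) markers list), normexp correction (Hba-a2), only probes above background on all arrays (pancreas markers list), only the compared groups fitted (Dbp, Hba-a2, Ly6d and Oas1a), quantile normalization (Hba-a2) and spike-in scaling (Hba-a2, fetal and tumour-associated liver genes list, interferon response list and pancreas markers list). Camera called 16 of the 32 lists in A/J, 1 with an estimated correlation.

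In C3H/HeJ livers, 23 of 27 extracellular matrix and stellate cell activation genes, 20 of 23 cell cycle genes and 12 of 14 fetal and tumour-associated liver genes rose on the deficient diet. Ly6d, a small surface protein, rose 608-fold (9.25 ± 0.83), Ubd (chromosome 17, 37332688 to 37332747), a ubiquitin-like modifier, rose 303-fold (8.25 ± 0.69, 3 of 4 control arrays above background) and Spink1, a trypsin inhibitor, rose 54.2-fold (5.76 ± 0.40, 3 of 4 control arrays above background). Cyp4a14, a fatty acid hydroxylase, rose by 5.79 ± 0.74 (3 of 4 control arrays above background) and Mogat1 by 6.10 ± 0.48 (1 of 4 control arrays above background). H19, an imprinted fetal transcript not well above background on the control diet, rose at least 33.1-fold (adjusted p = 8.7e-04), and Gpnmb, likewise below it there, rose at least 6.50-fold (adjusted p = 7.1e-06). Hnf4aos (-4.53 ± 0.44), Adgrf1 (-4.29 ± 0.38), Cspg5 (-4.05 ± 0.32) and Pax2 (-3.78 ± 0.64) were among the largest falls. Cdkn1a, the cell cycle inhibitor p21, rose by 3.81 ± 0.42 (2 of 4 control arrays above background), and its other probe by 0.77.

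Limma called 7524 of 15705 genes in C3H/HeJ, 2712 higher and 4812 lower on the deficient diet, and 5130 when only the groups compared shared the spread. Of simulated C3H/HeJ calls, not real ones, 40.6% were unchanged genes (8.39% with only its own groups fitted). The share of calls that were higher was 36.0%, 50.4% with quantile normalization, 48.5% with normexp correction and 91.5% with spike-in scaling. With slide as a fixed block 7743 genes were called in C3H/HeJ, and 7761 as a random one; within slides 1, 2 and 3, 17, 16 and 17 of the 17 called lists kept the sign of their median (17 lists called with the block).

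Of 18 lipid droplet and PPAR-gamma targets, 12 rose and 1 fell (14 and 1 adjusted over the list alone), median 1.17, adjusted p = 3.1e-07, adjusted p = 0.0269 with an estimated correlation. Cidec (4.86 ± 0.55), Cd36 (3.03 ± 0.25), Pparg (1.48 ± 0.22) and Plin2 (0.93 ± 0.15) rose. Of 26 fatty acid oxidation and ketogenesis genes, 8 rose and 2 fell (7 and 2 adjusted over the list alone), median 0.10, adjusted p = 0.0146, adjusted p = 0.601 with an estimated correlation. Vnn1 rose (4.27 ± 0.33). Of 22 fatty acid and triglyceride synthesis genes, 4 rose and 4 fell (3 and 2 adjusted over the list alone), median -0.075 (mean 0.050, camera direction up), adjusted p = 0.390. Fasn rose (1.04 ± 0.33). Of 21 lipoprotein assembly and clearance genes, 1 rose and 11 fell (1 and 12 adjusted over the list alone), median -0.48, adjusted p = 0.179. Mttp, the triglyceride transfer protein, fell (-0.66 ± 0.11) and Apoa4 rose (2.36 ± 0.25). Of 23 cholesterol synthesis genes, 0 rose and 5 fell (0 and 2 adjusted over the list alone), median -0.40, adjusted p = 0.298. Of 19 bile acid synthesis and transport genes, 1 rose and 13 fell (1 and 14 adjusted over the list alone), median -0.81, adjusted p = 0.00116, adjusted p = 0.537 with an estimated correlation. Abcb11, the bile salt export pump, fell (-1.0 ± 0.10). Of 35 methionine, folate and choline metabolism genes, 3 rose and 15 fell (3 and 15 adjusted over the list alone), median -0.32, adjusted p = 0.179. Gnmt (-1.53 ± 0.30) and Cbs (-1.02 ± 0.16) fell and Mthfd2 rose (2.36 ± 0.30, 2 of 4 control arrays above background). Of 13 DNA methylation enzymes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), median -0.11 (mean 0.35, camera direction up), adjusted p = 0.339. Leaving out 1 array ended the call of Fasn (without control 2 or deficient 3, 0.80 to 0.88, adjusted p = 0.0527 to 0.0611) and the fatty acid oxidation and ketogenesis list (without deficient 3 or 4, 0.020 to 0.041, adjusted p = 0.0634 to 0.0795). Calls were lost with, among others, 1 array fewer in each group (Fasn and fatty acid oxidation and ketogenesis list), array weights (fatty acid oxidation and ketogenesis list), only the compared groups fitted (Fasn) and spike-in scaling (Mttp).

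Of 27 extracellular matrix and stellate cell activation genes, 23 rose and 0 fell (23 and 0 adjusted over the list alone), median 1.32, adjusted p = 3.5e-12, adjusted p = 0.210 with an estimated correlation. Col1a1, a fibrillar collagen, rose 15.5-fold (3.96 ± 0.60) and Timp1 rose by 4.54 ± 0.58. Of 21 macrophage and monocyte markers, 17 rose and 0 fell (18 and 0 adjusted over the list alone), median 1.60, adjusted p = 5.3e-12, adjusted p = 0.126 with an estimated correlation. Trem2 (4.41 ± 0.48, 3 of 4 control arrays above background) and Cd68 (1.67 ± 0.22) rose. Of 16 chemokines and inflammatory mediators, 14 rose and 0 fell (14 and 0 adjusted over the list alone), median 2.29, adjusted p = 3.7e-10, adjusted p = 0.144 with an estimated correlation. Ccl2 rose by 4.48 ± 0.62. Of 15 lymphocyte markers, 8 rose and 2 fell (8 and 2 adjusted over the list alone), median 1.1, adjusted p = 0.0285, adjusted p = 0.601 with an estimated correlation. Of 6 neutrophil markers, 0 rose and 2 fell (0 and 3 adjusted over the list alone), median -0.36, adjusted p = 0.327. Of 13 biliary and progenitor markers, 7 rose and 0 fell (7 and 0 adjusted over the list alone), median 1.16, adjusted p = 4.5e-04, adjusted p = 0.346 with an estimated correlation. Spp1, osteopontin, rose (1.70 ± 0.42). Of 13 endothelial markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone), median -0.011 (mean 0.075, camera direction up), adjusted p = 0.546. Of 5 mesothelial markers, 1 (Krt8) rose and 0 fell (1 and 0 adjusted over the list alone), median 1.02, adjusted p = 0.0444, adjusted p = 0.350 with an estimated correlation. Of 23 cell cycle genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone), median 2.35, adjusted p = 1.5e-18, adjusted p = 0.0358 with an estimated correlation. Mki67 rose 7.98-fold (3.00 ± 0.28). Leaving out 1 array ended the call of the lymphocyte markers list (without deficient 1, 0.81, adjusted p = 0.112) and the mesothelial markers list (without control 4 or deficient 2 or 3, 0.85 to 0.96, adjusted p = 0.0628 to 0.0824). Calls ended with, among others, array weights (mesothelial markers list), the mean of all probes of a gene (mesothelial markers list), median centring (mesothelial markers list), normexp correction (lymphocyte markers list and mesothelial markers list), only probes above background on all arrays (lymphocyte markers list), quantile normalization (lymphocyte markers list and mesothelial markers list) and spike-in scaling (biliary and progenitor markers list, lymphocyte markers list and mesothelial markers list).

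Of 16 p53 and DNA damage response genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone), median 0.43, adjusted p = 9.2e-04, adjusted p = 0.144 with an estimated correlation. Of 20 unfolded protein and amino acid stress response genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone), median -0.34, adjusted p = 0.353. Of 23 oxidative stress and glutathione genes, 7 rose and 9 fell (8 and 9 adjusted over the list alone), median 0.056, adjusted p = 0.327. Of 20 drug-metabolising cytochromes, 0 rose and 16 fell (1 and 16 adjusted over the list alone), median -0.87, adjusted p = 4.3e-04, adjusted p = 0.537 with an estimated correlation. Cyp2c29 fell (-2.06 ± 0.24). Of 14 male-biased liver genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone), median -0.98, adjusted p = 4.5e-04, adjusted p = 0.350 with an estimated correlation. Hsd3b5 (-2.36 ± 0.41) and Elovl3 (-2.93 ± 0.55) fell. Of 10 female-biased liver genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), median 1.35, adjusted p = 0.00632, adjusted p = 0.371 with an estimated correlation. Cyp2b9 rose (3.12 ± 0.55). Of 23 hepatocyte function genes, 0 rose and 18 fell (0 and 18 adjusted over the list alone), median -0.71, adjusted p = 1.0e-04, adjusted p = 0.548 with an estimated correlation. F7 (-1.17 ± 0.15) and Alb (-0.49 ± 0.15, opposite in sign with spike-in scaling) fell. Of 17 acute phase response genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone), median -0.55, adjusted p = 0.168. Lcn2 rose (4.05 ± 0.48). Without 1 array the call was lost for Alb (without control 4 or deficient 2, -0.36, adjusted p = 0.0597 to 0.0685). Settings that ended calls included normexp correction (Alb and female-biased liver genes list), only probes above background on all arrays (female-biased liver genes list), only the compared groups fitted (Alb), quantile normalization (Alb) and spike-in scaling (Alb and female-biased liver genes list).

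Of 14 fetal and tumour-associated liver genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), median 2.47, adjusted p = 8.0e-10, adjusted p = 0.126 with an estimated correlation. Afp rose (2.17 ± 0.27). Of 18 circadian clock genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), median -0.32, adjusted p = 0.327. Nfil3 fell (-1.01 ± 0.20). Of 20 interferon response genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone), median 0.84, adjusted p = 5.5e-04, adjusted p = 0.535 with an estimated correlation. Oas1a rose (1.00 ± 0.22). Of 18 iron handling genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), median -0.25, adjusted p = 0.339. Of 10 pancreas markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone), median -0.40 (mean -0.37, camera direction up), adjusted p = 0.922. Of 5 adipose tissue markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone), median -0.69 (mean 0.20, camera direction up), adjusted p = 0.949. Of 5 blood cell (erythroid) markers, 0 rose and 5 fell (0 and 5 adjusted over the list alone), median -0.90, adjusted p = 0.0851. Hba-a2 fell (-0.90 ± 0.22). Calls were lost with, among others, normexp correction (Hba-a2), quantile normalization (Hba-a2) and spike-in scaling (Hba-a2). Camera called 17 lists in C3H/HeJ, 2 with an estimated correlation.

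In WSB/EiJ livers, 23 of 23 hepatocyte function genes, 20 of 20 drug-metabolising cytochromes and 18 of 19 bile acid synthesis and transport genes fell, while 18 of 21 macrophage and monocyte markers, 21 of 23 cell cycle genes and 17 of 20 interferon response genes rose. Ly6d (chromosome 15, 74592551 to 74592610) rose 888-fold (9.79 ± 0.83), Ifi27l2b, an interferon-inducible gene, rose 394-fold (8.62 ± 0.37, 5.67 on its other probe) and H19 rose 288-fold (8.17 ± 1.22). Gpnmb and Itgax, markers of lipid-associated macrophages and dendritic cells that were not well above background on the control diet, rose at least 135-fold and at least 76.4-fold (adjusted p = 5.4e-10 and adjusted p = 2.0e-08). Cyp2c54 (chromosome 19, 40112528 to 40112587) and Cyp2c50, drug-metabolising cytochromes of near-identical sequence, so that cross-hybridisation cannot be ruled out, were at -7.81 ± 0.38 and -7.74 ± 0.40, and other Cyp2c54 probes at -7.48 and -3.54. Nuggc (-7.64 ± 0.36), Elovl3, an elongase (-7.50 ± 0.55), and Pax2 (-7.21 ± 0.64) fell, and Fgf21 rose 92.5-fold (6.53 ± 0.47).

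Limma called 11552 of 15705 genes in WSB/EiJ, 3701 higher and 7851 lower on the deficient diet, and 11904 when only the groups compared shared the spread. The share of calls that were higher was 32%, 47.9% with quantile normalization, 48.5% with normexp correction and 88.4% with spike-in scaling, so the direction of the small falls depends on the scaling. The median of all genes was -0.33 in WSB/EiJ, -0.16 in C3H/HeJ and -0.066 in A/J, and 0.62, 0.36 and 0.31 with spike-in scaling. With quantile normalization these medians were -0.051, -0.027 and 0.0024. With slide as a fixed block 11555 genes were called in WSB/EiJ, and 11630 as a random one; within slides 1, 2 and 3, 16, 16 and 16 of the 16 called lists kept the sign of their median (16 lists called with the block).

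Of 18 lipid droplet and PPAR-gamma targets, 8 rose and 5 fell (8 and 5 adjusted over the list alone), median 0.49, adjusted p = 0.0277, adjusted p = 0.251 with an estimated correlation. Cidec rose 49.7-fold (5.64 ± 0.55). Of 26 fatty acid oxidation and ketogenesis genes, 4 rose and 16 fell (4 and 16 adjusted over the list alone), median -0.68 (mean 0.10, camera direction down), adjusted p = 0.476. Cyp4a14 rose (5.52 ± 0.74, 3 of 4 control arrays above background). Of 22 fatty acid and triglyceride synthesis genes, 4 rose and 10 fell (3 and 10 adjusted over the list alone), median -0.60, adjusted p = 0.792. Fasn was at -0.27 ± 0.33, opposite in sign with spike-in scaling, adjusted p = 0.464. Of 21 lipoprotein assembly and clearance genes, 4 rose and 16 fell (4 and 16 adjusted over the list alone), median -1.08, adjusted p = 0.0547. Apoa4 rose (3.74 ± 0.25), and Mttp (-1.02 ± 0.11) and Apob (-0.91 ± 0.14, opposite in sign with spike-in scaling) fell. Of 23 cholesterol synthesis genes, 0 rose and 22 fell (0 and 22 adjusted over the list alone), median -1.26, adjusted p = 0.00305, adjusted p = 0.755 with an estimated correlation. Tm7sf2, a sterol reductase, fell (-2.52 ± 0.26). Of 19 bile acid synthesis and transport genes, 1 rose and 18 fell (1 and 18 adjusted over the list alone), median -1.88, adjusted p = 7.3e-05, adjusted p = 0.362 with an estimated correlation. Cyp8b1 (-3.29 ± 0.44), Cyp7a1 (-2.51 ± 0.48) and Abcb11 (-1.31 ± 0.10) fell, and Slc10a1, the bile acid uptake carrier (-0.60 ± 0.099, opposite in sign with quantile normalization, normexp correction and spike-in scaling), fell, its other probe being at -2.56. Of 35 methionine, folate and choline metabolism genes, 3 rose and 23 fell (3 and 23 adjusted over the list alone), median -0.97, adjusted p = 0.0182, adjusted p = 0.755 with an estimated correlation. Gnmt (-2.21 ± 0.30), Bhmt (-1.62 ± 0.22) and Mat1a (-1.58 ± 0.27) fell, and Pemt, which makes phosphatidylcholine, fell (-0.70 ± 0.14, opposite in sign with quantile normalization, normexp correction and spike-in scaling). Of 13 DNA methylation enzymes, 5 rose and 4 fell (5 and 4 adjusted over the list alone), median -0.13 (mean 0.16, camera direction up), adjusted p = 0.528. Calls ended with, among others, normexp correction (Apob and Pemt), quantile normalization (Apob and Pemt) and spike-in scaling (Apob, Mttp and lipid droplet and PPAR-gamma targets list).

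Of 27 extracellular matrix and stellate cell activation genes, 24 rose and 1 fell (24 and 1 adjusted over the list alone), median 1.91, adjusted p = 7.5e-12, adjusted p = 0.215 with an estimated correlation. Col1a1 rose 44.8-fold (5.49 ± 0.60), Col3a1 by 4.00 ± 0.43 and Timp1 by 6.41 ± 0.58 (3 of 4 control arrays above background). Of 21 macrophage and monocyte markers, 18 rose and 0 fell (18 and 0 adjusted over the list alone), median 4.15, adjusted p = 2.4e-12, adjusted p = 0.111 with an estimated correlation. Trem2 (7.75 ± 0.48) and Cd68 (4.15 ± 0.22) rose. Of 16 chemokines and inflammatory mediators, 14 rose and 0 fell (14 and 0 adjusted over the list alone), median 3.23, adjusted p = 7.3e-08, adjusted p = 0.215 with an estimated correlation. Ccl2 rose (5.17 ± 0.62). Of 15 lymphocyte markers, 7 rose and 4 fell (7 and 4 adjusted over the list alone), median 0.94, adjusted p = 0.0834. Slides 1, 2 and 3 gave medians of 0.27, 0.25 and 2.36. Of 6 neutrophil markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone), median -0.66, adjusted p = 0.634. Of 13 biliary and progenitor markers, 11 rose and 0 fell (11 and 0 adjusted over the list alone), median 2.33, adjusted p = 4.4e-05, adjusted p = 0.215 with an estimated correlation. Spp1 (3.06 ± 0.42) and Krt19 (2.33 ± 0.51) rose. Of 13 endothelial markers, 3 rose and 5 fell (3 and 5 adjusted over the list alone), median -0.18 (mean -0.096, camera direction up), adjusted p = 0.794. Of 5 mesothelial markers, 3 rose (Krt8, 1.74 ± 0.15) and 0 fell (3 and 0 adjusted over the list alone), median 1.74, adjusted p = 0.0229, adjusted p = 0.251 with an estimated correlation. Of 23 cell cycle genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone), median 2.89, adjusted p = 3.2e-13, adjusted p = 0.111 with an estimated correlation. Mki67 rose 24.7-fold (4.63 ± 0.28). Spike-in scaling ended the mesothelial list call.

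Of 16 p53 and DNA damage response genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone), median 1.06, adjusted p = 1.1e-05, adjusted p = 0.111 with an estimated correlation. Cdkn1a rose (1.32 ± 0.42, 2.30 on its other probe). Of 20 unfolded protein and amino acid stress response genes, 4 rose and 11 fell (4 and 11 adjusted over the list alone), median -0.54 (mean 0.067, camera direction down), adjusted p = 0.840. Of 23 oxidative stress and glutathione genes, 5 rose and 13 fell (5 and 13 adjusted over the list alone), median -0.63, adjusted p = 0.637. Of 20 drug-metabolising cytochromes, 0 rose and 20 fell (0 and 20 adjusted over the list alone), median -2.54, adjusted p = 5.8e-07, adjusted p = 0.295 with an estimated correlation. Cyp2c29 fell (-2.89 ± 0.24). Of 14 male-biased liver genes, 0 rose and 13 fell (0 and 13 adjusted over the list alone), median -2.51, adjusted p = 7.3e-05, adjusted p = 0.251 with an estimated correlation. Hsd3b5 fell (-5.97 ± 0.41). Of 10 female-biased liver genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone), median 0.57, adjusted p = 0.506. Cyp2b9 fell (-3.59 ± 0.55, 1 of 4 deficient arrays above background). Of 23 hepatocyte function genes, 0 rose and 23 fell (0 and 23 adjusted over the list alone), median -1.33, adjusted p = 4.4e-05, adjusted p = 0.564 with an estimated correlation. F7 (-1.86 ± 0.15) and Alb (-1.0 ± 0.15, opposite in sign with quantile normalization) fell. Of 17 acute phase response genes, 3 rose and 12 fell (3 and 12 adjusted over the list alone), median -0.80, adjusted p = 0.476. Lcn2 rose (5.05 ± 0.48). Settings that ended calls included normexp correction (Alb), quantile normalization (Alb) and spike-in scaling (Alb).

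Of 14 fetal and tumour-associated liver genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), median 3.69, adjusted p = 5.6e-09, adjusted p = 0.164 with an estimated correlation. Afp rose 16.4-fold (4.03 ± 0.27). Of 18 circadian clock genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone), median -0.80, adjusted p = 0.187. Hlf fell (-2.15 ± 0.26). Of 20 interferon response genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone), median 2.67, adjusted p = 4.3e-10, adjusted p = 0.201 with an estimated correlation. Oas1a rose 41-fold (5.36 ± 0.22). Of 18 iron handling genes, 3 rose and 8 fell (3 and 8 adjusted over the list alone), median -0.17, adjusted p = 0.895. Of 10 pancreas markers, 4 rose and 0 fell (4 and 0 adjusted over the list alone), median 1.1, adjusted p = 0.0874. Slides 1, 2 and 3 gave medians of 0.21, -0.38 and 2.86, and 0.11 without deficient 4. Of 5 adipose tissue markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone), median -0.68, adjusted p = 0.794. Of 5 blood cell (erythroid) markers, 0 rose and 4 fell (0 and 4 adjusted over the list alone), median -0.93, adjusted p = 0.435. Hba-a2 fell (-1.0 ± 0.22). Calls were lost with, among others, normexp correction (Hba-a2), quantile normalization (Hba-a2) and spike-in scaling (Hba-a2). Camera called 16 lists in WSB/EiJ, 0 with an estimated correlation, and fry called 28 of 32.

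**Figure D1:**
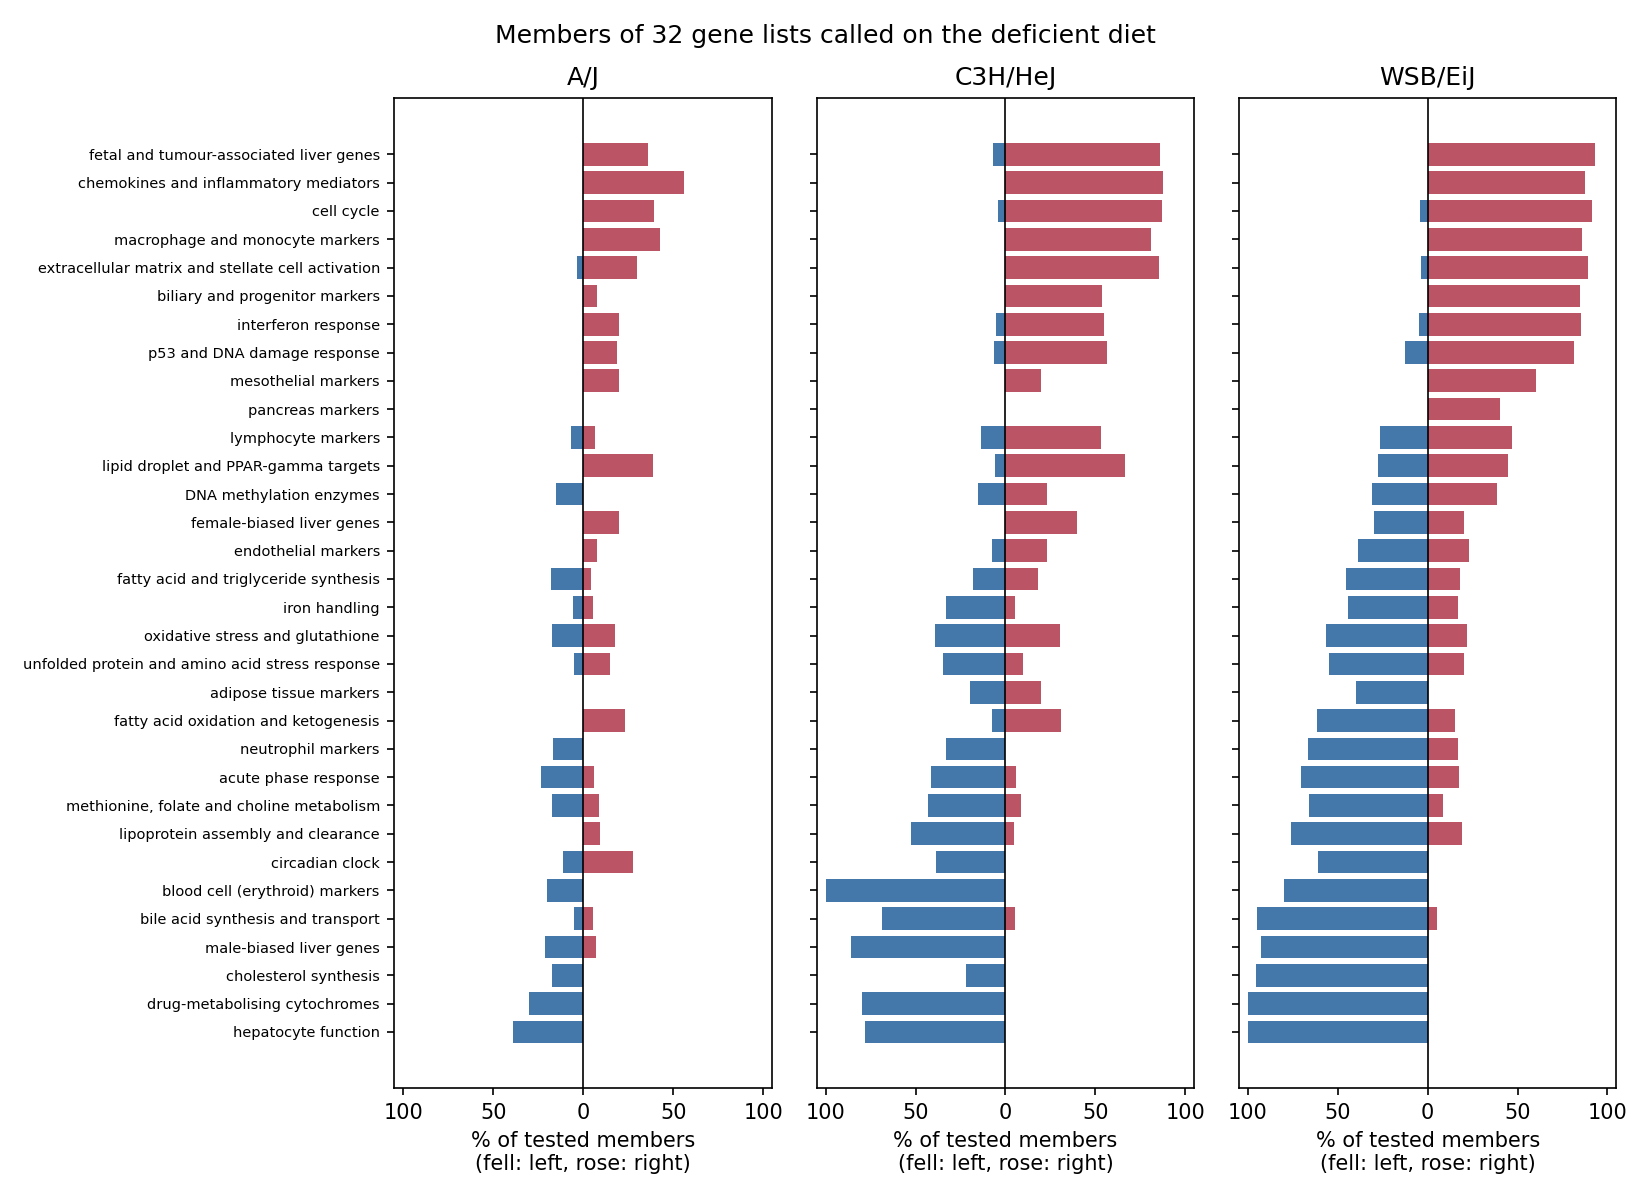
Percent of the tested members of each of 32 gene lists that fell (left, blue) or rose (right, red) on the deficient diet, by limma adjusted p, in each strain. In WSB/EiJ, 23 of 23 hepatocyte function genes fell and 18 of 21 macrophage and monocyte markers rose with arrays scaled on their 75th percentile; with spike-in scaling the median of all genes was higher, not lower, on the deficient diet.

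Called in the same direction in all 3 strains were a rise of Ly6d, Ubd, Ifi27l2b, Trem2, Rad51b and Spink1 and a fall of Cyp2c38, Slc13a2, Elovl3, Serpina4-ps1, Cyp2c54 and Cyp2c50. Rad51b (chromosome 12, 80915000 to 80915059) rose by 4.00 ± 0.30 in A/J, 5.79 ± 0.30 (3 of 4 control arrays above background) in C3H/HeJ and 6.0 ± 0.30 in WSB/EiJ, and Slc13a2 was at -3.22 ± 0.48, -3.63 ± 0.48 and -6.63 ± 0.48. A second Cyp2c38 probe was at 0.31, 2.15 and 0.62, so that the direction of this gene depends on the probe. In all, 1171 genes were called alike in all 3 strains (629 higher, 542 lower), where independent lists would share 147, and 566 with only the groups compared in each fit. The count was 550 to 751 without A/J deficient 1 or 3 or control 1 or 3, and 3229 to 3695 with array weights, spike-in scaling or 1 array fewer in each group. Acot1, Sqle, Tfrc and Hamp, fixed before the data were examined, passed in none of the strains (Tfrc at 1.05 on its other probe in WSB/EiJ). Across genes, which are not independent replicates, the diet effects correlated with Pearson's r of 0.685 for C3H/HeJ and A/J, 0.616 for WSB/EiJ and A/J and 0.814 for WSB/EiJ and C3H/HeJ (Spearman's rho 0.625, 0.571 and 0.777). A single array decided the call of Cyp2c50 (without control 1, 2 or 3 or deficient 1, 2 or 3, -1.39 to -1.11, adjusted p = 0.0605 to 0.141) and Cyp2c54 (without control 1, 2 or 3 or deficient 1, 2 or 3, -1.36 to -1.16, adjusted p = 0.0556 to 0.108). Calls ended with, among others, the mean of all probes of a gene (Cyp2c38), no background filter (Cyp2c50 and Cyp2c54), only the compared groups fitted (Ly6d) and quantile normalization (Cyp2c50).

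**Figure D2:**
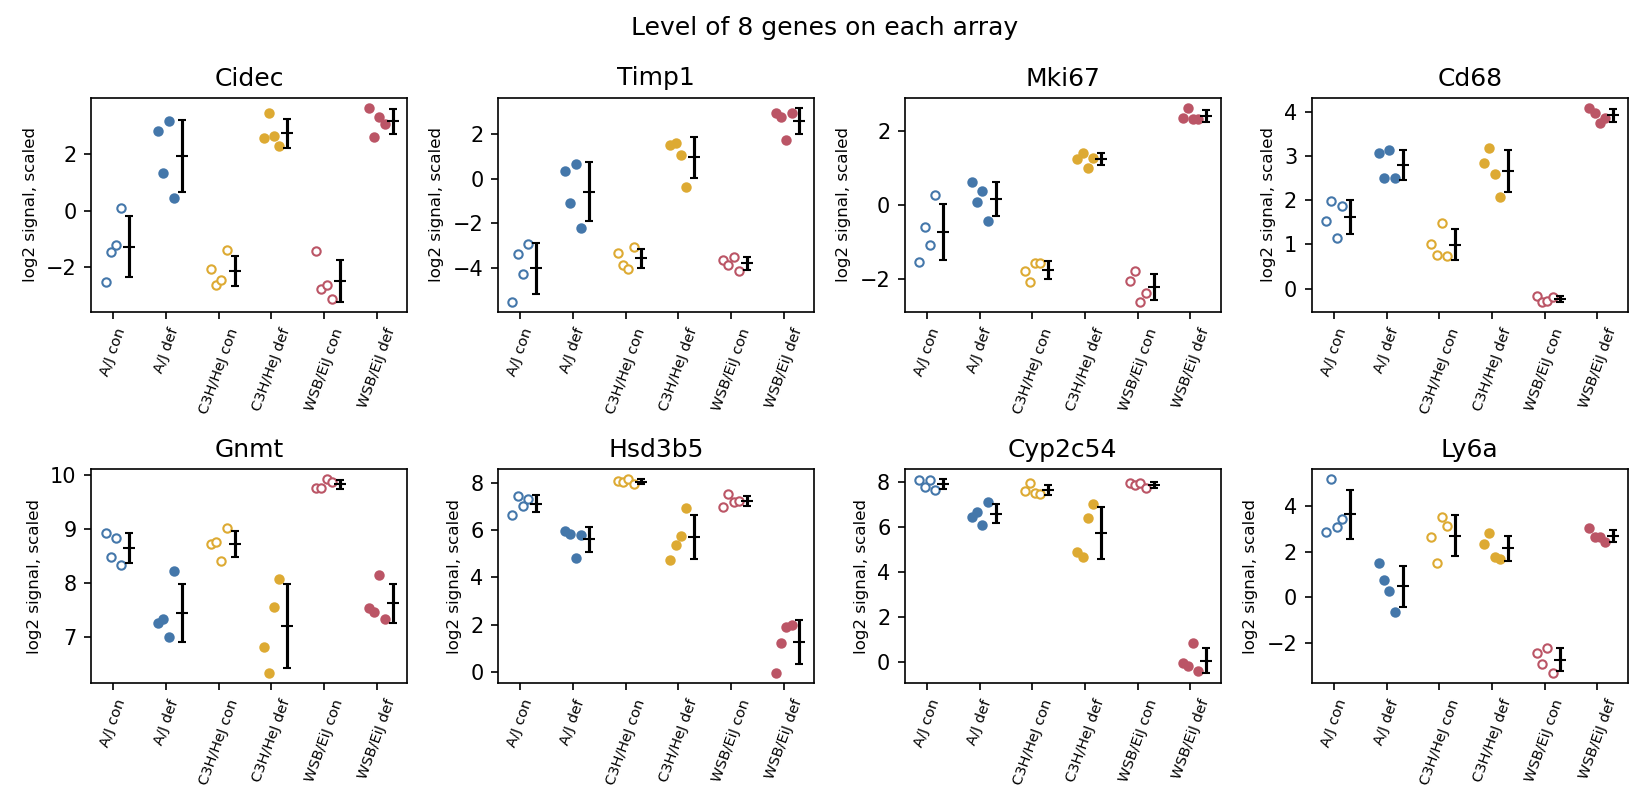
Scaled log2 signal of 8 genes on each array (open, control diet; filled, deficient diet), with the mean and SD of the 4 arrays of each group beside them. Cyp2c54 and Hsd3b5 were lowest on the WSB/EiJ deficient arrays.

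The strains differed in how far, and for some genes in which direction, the diet moved expression. Ly6a, a surface protein induced by interferon, fell in A/J (-3.16 ± 0.50) and rose in WSB/EiJ (5.44 ± 0.50), a difference of 8.59 ± 0.70. The falls of Nuggc, Cyp2c54 and Cyp2c50 in WSB/EiJ differed from the change in A/J by -7.97 ± 0.51, -6.49 ± 0.54 and -6.43 ± 0.57, and the diet effect on Csn3, a milk casein, was higher in WSB/EiJ than in C3H/HeJ by 4.73 ± 0.48 (3 of 4 C3H/HeJ control arrays above background, 3 of 4 C3H/HeJ deficient arrays above background). Ubd (4.49 ± 0.97, 3 of 4 C3H/HeJ control arrays above background), Cyp4a14 (3.82 ± 1.04, 3 of 4 C3H/HeJ control arrays above background) and the class II genes H2-Eb1 (3.81 ± 0.82) and H2-Ab1 (3.71 ± 0.74), which present antigen, had a higher diet effect in C3H/HeJ than in A/J. Mki67 rose more in WSB/EiJ than in A/J by 3.74 ± 0.40. Of 20 interferon response genes, 18 had a higher effect in WSB/EiJ than in A/J (18 adjusted over the list alone), with a median difference of 2.5, adjusted p = 4.5e-12 and adjusted p = 0.128 with an estimated correlation. Leaving out 1 array ended the call of Cyp4a14 (without A/J control 1, 3 or 4 or A/J deficient 1, 2, 3 or 4 or C3H/HeJ control 1, 2 or 4 or C3H/HeJ deficient 2 or 3, 3.30 to 3.93, adjusted p = 0.0586 to 0.0943). Settings that ended calls included 1 array fewer in each group (Cyp4a14), array weights (Cyp4a14), no background filter (Cyp4a14), normexp correction (Cyp4a14), only the compared groups fitted (H2-Eb1 and Ubd), unnamed probes included (Cyp4a14), quantile normalization (Cyp4a14) and spike-in scaling (Cyp4a14).

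The test of the difference called 547 genes between C3H/HeJ and A/J (323 higher, 224 lower), 7878 between WSB/EiJ and A/J (2592 and 5286) and 4039 between WSB/EiJ and C3H/HeJ (1434 and 2605), and the F test over the strains called 7165. The C3H/HeJ and A/J count was 1935 without C3H/HeJ deficient 4, and 321 to 342 without deficient 2 or 4 of A/J or 1 or 2 of C3H/HeJ. With slide as a fixed block the 3 differences called 451, 7488 and 3946 genes. The share of the differing genes with a higher effect was 59.0% for C3H/HeJ against A/J (73% with spike-in scaling, 49.5% with 1 array fewer in each group, 40.2% with array weights, 47.1% with only probes above background on all arrays and 43.1% without C3H/HeJ deficient 4), 32.9% for WSB/EiJ against A/J (49.4% with quantile normalization, 51.4% with normexp correction and 80.6% with spike-in scaling) and 35.5% for WSB/EiJ against C3H/HeJ (53.5% with quantile normalization, 59.3% with normexp correction and 81.8% with spike-in scaling). Camera called 16, 16 and 17 lists for these differences, and 1, 0 and 0 with an estimated correlation.

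**Figure D3:**
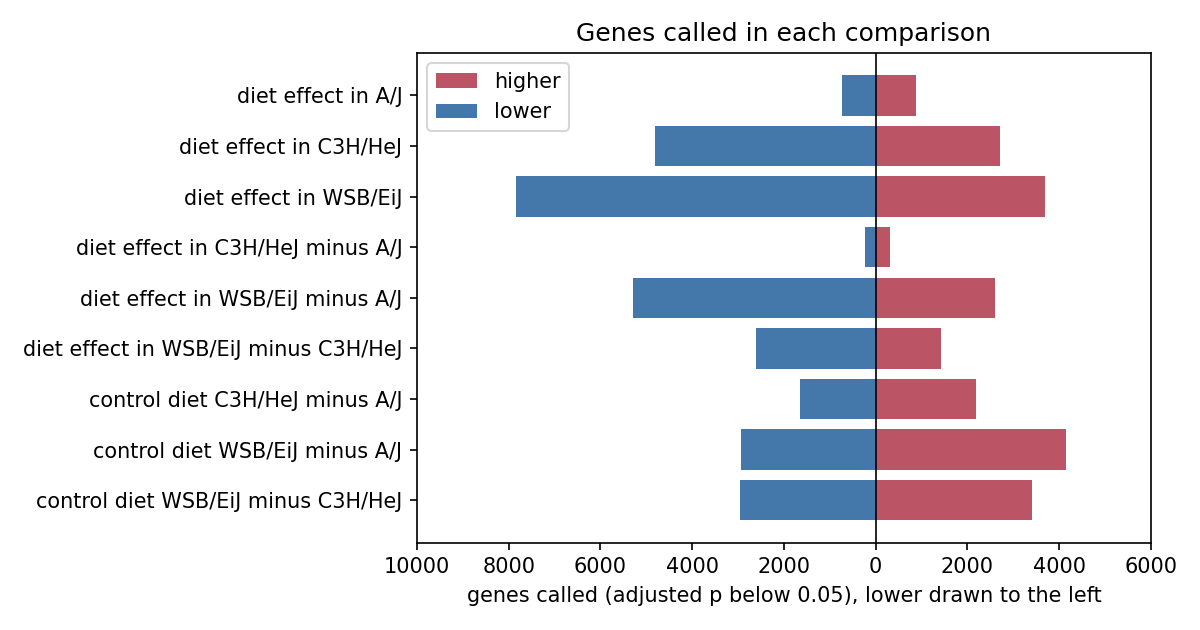
Number of genes called by limma in each comparison, higher drawn to the right (red) and lower to the left (blue), at an adjusted p threshold of 0.05. WSB/EiJ had the most calls (11552) and A/J the fewest (1612) among the diet effects.

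On the control diet the strains already differed, in single genes of sulfation, fatty acid hydroxylation and antigen presentation. Sult1e1, an oestrogen sulfotransferase, was higher in WSB/EiJ than in A/J by 7.58 ± 0.48 and than in C3H/HeJ by 7.91 ± 0.48 (3 of 4 C3H/HeJ control arrays above background), and Nat8f5 by 6.40 ± 0.33 and 6.26 ± 0.33. Nnmt, nicotinamide methyltransferase, was higher in WSB/EiJ than in A/J by 5.86 ± 0.67. Cyp4a14 was lower in C3H/HeJ (-8.48 ± 0.74, 3 of 4 C3H/HeJ control arrays above background) and in WSB/EiJ (-8.59 ± 0.74, 3 of 4 WSB/EiJ control arrays above background) than in A/J, and H2-Eb1 was lower in WSB/EiJ than in A/J (-7.31 ± 0.58), as was Hamp2 (-6.83 ± 0.79). Dct, a pigment enzyme (5.06 ± 0.67), Bmf (4.77 ± 0.37) and Fmn1 (4.19 ± 0.34) were higher in C3H/HeJ than in A/J, and Hsd17b13 (-4.70 ± 0.13) and Cyp2b9 (-4.32 ± 0.55) lower, Hsd17b13 at 0.25 when all probes of the gene were averaged. The clock output gene Dbp (-6.88 ± 0.58), Cyp39a1 (-6.56 ± 0.36) and Igsf23 (-5.60 ± 0.26, 3 of 4 WSB/EiJ control arrays above background) were lower in WSB/EiJ than in C3H/HeJ, and H2-Q3 (5.77 ± 0.45, 3 of 4 C3H/HeJ control arrays above background) higher. Limma called 3847 genes between C3H/HeJ and A/J, 7080 between WSB/EiJ and A/J and 6362 between WSB/EiJ and C3H/HeJ, and 3880, 7111 and 6434 with slide as a fixed block. With spike-in scaling the share of these calls that was higher in WSB/EiJ was 32.5% against A/J (75th percentile 58.5%) and 33.4% against C3H/HeJ (53.5%); quantile normalization gave 49.3 and 48.0%, and normexp correction 46.7% against C3H/HeJ. A sequence difference between strains under a probe gives such a difference too, and the mean of clock genes with E-box or D-box elements minus that of clock genes with RORE elements was -0.16 ± 0.99 in A/J, 2.06 ± 0.41 in C3H/HeJ and -2.06 ± 0.28 in WSB/EiJ on the control diet (SD, n = 4). The mean of all probes of a gene ended the call of Hsd17b13.

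**Figure D4:**
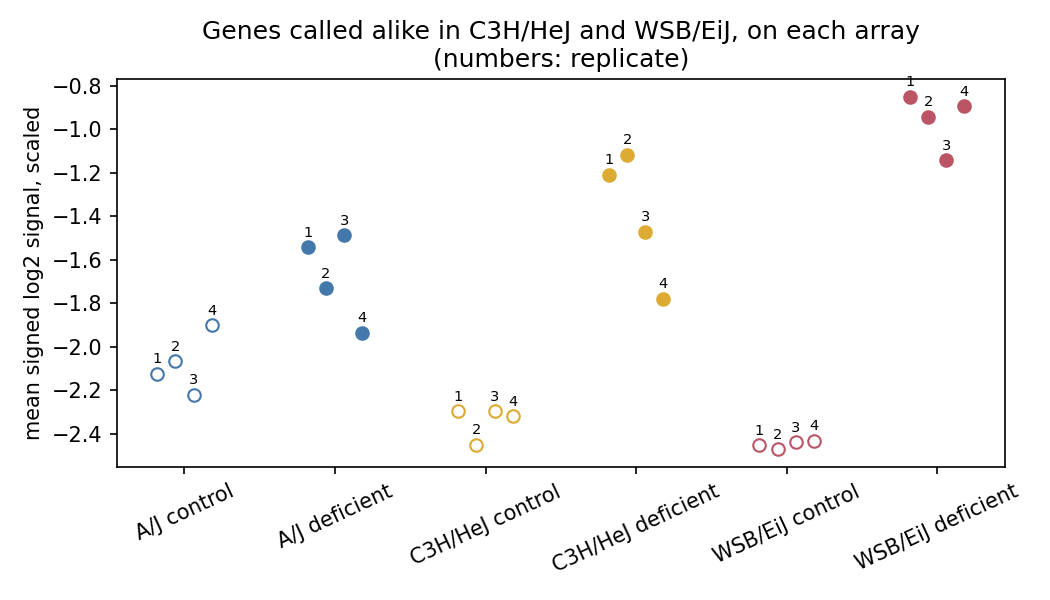
Mean signed log2 signal of the 6583 genes called alike in C3H/HeJ and WSB/EiJ, on each array (open, control diet; filled, deficient diet; numbers, replicate). A/J control replicate 4 (-1.90) and deficient replicate 4 (-1.94) lie side by side.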

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

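Tests of explanations, comparisons with other splits and the use of unnamed probes were chosen after the results were seen, tests of a difference between strains before. By the F test the diet effect differed between strains for 56 of 74 genes followed, partly chosen for this, and 7165 of all 15705. As the effect in WSB/EiJ minus that in A/J, it was higher in WSB/EiJ for Ly6a (8.59), H19 (8.14), Ifi27l2b (5.01), Csn3 (4.89), Ly6d (4.57), Gpnmb (4.53), Oas1a (4.21), Fgf21 (4.13), Spink1 (3.99), Mki67 (3.74), Col1a1 (3.64), Afp (3.63), Cyp4a14 (3.54), Itgax (3.46), Ubd (3.38), Trem2 (3.23), H2-Eb1 (2.98), Cd68 (2.98), Timp1 (2.96), H2-Ab1 (2.93), Nrg1 (2.92), Col3a1 (2.74), Krt19 (2.71), Cidec (2.43), Spp1 (2.35), Rad51b (2.00), Mthfd2 (1.46), Krt8 (1.23) and Ccnd1 (0.91). It was lower for Nuggc (-7.97), Cyp2c54 (-6.49), Cyp2c50 (-6.43), Pax2 (-5.96), Cyp2c38 (-5.18), Elovl3 (-4.80), Hsd3b5 (-4.46), Cyp2b9 (-4.05), Slc13a2 (-3.40), Dbp (-2.64), Cyp8b1 (-2.63), Hlf (-2.60), Mogat1 (-2.42), Cspg5 (-1.98), Tm7sf2 (-1.63), Cyp2c29 (-1.42), Mat1a (-1.40), F7 (-1.07), Abcb11 (-0.99), Bhmt (-0.78), Mttp (-0.78) and Apob (-0.77). This difference did not itself pass for Apoa4 (0.10), Fasn (0.79), Cdkn1a (1.38), Adgrf1 (-1.24) and Hnf4aos (-0.19). Gpnmb and Itgax were not well above background in at least 1 group, so their differences are not bounds. Mogat1, Cyp4a14, Mthfd2, Timp1, Trem2, Cyp2b9, H19, Ubd, Nrg1 and Spink1 were above background on only some arrays of a group, and A/J control 4 stood apart for H19 and Ly6d, so their sizes are uncertain.

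In 34 of 510 groups of 4 arrays (6.67%), 1 array stood apart from the others by Dixon's ratio in its scaled log2 signal. Chance gives about 1 in 20. WSB/EiJ deficient 3 stood apart for Pparg (0.70, others 0.96 to 1.00), Fgf21 (3.41, others 4.58 to 4.65), Timp1 (1.74, others 2.79 to 2.96), Trem2 (4.22, others 4.67 to 4.71), Cyp2c50 (1.14, others -0.30 to -0.10), H2-Ab1 (5.91, others 6.52 to 6.56), Dct (-0.36, others -1.21 to -1.07), Bmf (-0.10, others 0.76 to 0.87) and Hsd17b13 (7.35, others 7.13 to 7.15). A/J control 4 stood apart for Mttp (4.21, others 4.42 to 4.44), Mthfd2 (-3.42, others -3.99 to -3.90), H19 (3.73, others -4.89 to -3.88) and Ly6d (2.64, others -2.80 to -2.30). C3H/HeJ deficient 4 stood apart for Mogat1 (-0.26, others 1.59 to 1.81), Fgf21 (2.09, others 3.04 to 3.09), Rad51b (1.73, others 2.75 to 2.85) and Cspg5 (0.20, others -1.63 to -1.41). WSB/EiJ control 3 stood apart for Slc13a2 (4.57, others 3.69 to 3.83), Nnmt (4.93, others 4.77 to 4.79) and Dbp (1.01, others 0.20 to 0.33). Other arrays were A/J deficient 3 for Spp1 (3.22, others 2.33 to 2.47) and Hsd3b5 (4.81, others 5.79 to 5.96); C3H/HeJ control 2 for Mat1a (6.35, others 7.12 to 7.26) and Cyp2c50 (7.58, others 7.06 to 7.12); C3H/HeJ control 4 for Pparg (-1.90, others -1.68 to -1.66) and Slc10a1 (9.88, others 9.59 to 9.63); WSB/EiJ deficient 2 for Mki67 (2.63, others 2.31 to 2.36) and Nfil3 (3.99, others 3.61 to 3.66). Further arrays were A/J deficient 1 for Nfil3 (2.35, others 3.10 to 3.13); A/J deficient 2 for Dct (0.037, others -0.57 to -0.51); C3H/HeJ control 1 for Igsf23 (1.12, others 2.18 to 2.24); WSB/EiJ control 1 for Ubd (-5.32, others -3.54 to -3.31). WSB/EiJ control 4 stood apart for Tm7sf2 (6.26, others 6.83 to 6.94) and deficient 1 for Hamp2 (1.02, others -2.17 to -1.80).

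Of 7252 probes above background that carry no gene name, limma called 340 in A/J, 2730 in C3H/HeJ and 5040 in WSB/EiJ, tested together with the named probes.

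Only the real split of 35 reached the number of genes called by diet in each strain (1612, 7524 and 11552 genes in A/J, C3H/HeJ and WSB/EiJ, highest other split 985, 4269 and 13). The same held for the differences between strains (547, 7878 and 4039, highest other 0, 0 and 1) and for the control diet (3847, 7080 and 6362, highest other 11, 12 and 246). This 1 of 35 is the least possible and cannot exclude chance. Chance stays open for the number of gene lists called: 9, 9 and 14 of 35 splits gave as many (16, 17 and 16 lists, highest other 21, 21 and 18). Of 100 splits, 1, the real one, reached the F test's count (7165, highest other 6727), the genes called alike in all 3 strains (1171, highest other 0) and the correlations of diet effects across genes (0.685, 0.616 and 0.814, highest other 0.633, 0.592 and 0.799).

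Fewer genes were called in A/J than in WSB/EiJ (11552). Spread factors were 0.986 (control) and 0.981 (deficient) in A/J, 0.802 and 0.888 in WSB/EiJ. The SD of diet effects across genes net of pooled errors, 3.08 times as large in WSB/EiJ, argues against spread as whole cause. The 2182 genes called without A/J deficient 4 argue against its wrong label as whole cause. With 1 array fewer in each group (both A/J replicate 4 out) A/J had 4625 calls (WSB/EiJ 11829), and 4036 (12623) with array weights. An exchange of their labels stays open. Both arrays lay together on genes called alike in other strains (-1.90 and -1.94), and Ly6d was high on control 4. But the exchange gave fewer genes (985, not 1612), and each was closest to one of its own group. A weaker response of A/J livers stays open as a hypothesis, since no other measure of injury is in the files.

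More genes were lower than higher on the deficient diet in WSB/EiJ. Scaling to the 75th percentile may be the source, since 88.4% of calls were higher with spike-in scaling. A gain that raised all spots of the deficient arrays alike is argued against by the spike-in mean, which differed by 0.0874 (log2) between the diets where the 75th percentile differed by 1.04. The 75th percentile over the spike-ins rose by 0.37 in A/J, 0.52 in C3H/HeJ (exact permutation p = 0.0571 in both) and 0.95 in WSB/EiJ (exact permutation p = 0.0286, the smallest 4 against 4 arrays can give; 2-sided). More labelled transcript per amount of RNA on the deficient diet, or another ratio of spike-in to RNA, stays open, as the files cannot separate them.

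Hepatocyte genes were lower and macrophage genes higher on the deficient diet in WSB/EiJ. The hepatocyte median, -1.33, was -0.37 with spike-in scaling, so the size of the fall and its number of genes depend on scaling. A lower share of hepatocytes alone is argued against, since it raises the markers of all other cells alike and the macrophage list rose by 3.93 (log2) more than the endothelial list. More macrophages, higher expression per macrophage, or lower expression per hepatocyte stay open as hypotheses.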

How the results depend on the processing

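Spike-in scaling, inclusion of unnamed probes and 1 array fewer in each group were chosen only after the data were seen, and the other alternatives before. Of 9918 values of panel and named genes over all alternatives, 9407 kept their sign and their side of the threshold, 279 lost a call, 126 gained one and 106 changed sign, 34 of them called before or after. Counts of genes and lists not given in this part stayed within 1.5 times the value reported. For the changes that follow the cause was not tested, except where stated. The tests of lists for differences between strains were not repeated under the alternatives.

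Spike-in scaling reversed the sign of Alb (0.027), Apob (0.24), Dnmt3b (0.29), Mat1a (0.52), Pemt (0.12) and Slc10a1 (0.11) in C3H/HeJ; Apob (0.23), Cdkn1a (0.30), Mat1a (0.19), Mttp (0.12), Pemt (0.10) and Slc10a1 (0.11) in A/J; Apob (0.045), Dnmt3b (0.74), Fasn (0.68), Pemt (0.25) and Slc10a1 (0.36) in WSB/EiJ, and the list medians in C3H/HeJ of DNA methylation enzymes (0.41), cholesterol synthesis (0.12), circadian clock (0.20), endothelial markers (0.51), fatty acid and triglyceride synthesis (0.44), iron handling (0.27), lipoprotein assembly and clearance (0.037), methionine, folate and choline metabolism (0.20), neutrophil markers (0.15), pancreas markers (0.12) and unfolded protein and amino acid stress response (0.18); in WSB/EiJ of DNA methylation enzymes (0.82), acute phase response (0.15), adipose tissue markers (0.28), blood cell (erythroid) markers (0.023), circadian clock (0.15), endothelial markers (0.77), fatty acid and triglyceride synthesis (0.35), fatty acid oxidation and ketogenesis (0.28), iron handling (0.78), neutrophil markers (0.30), oxidative stress and glutathione (0.33) and unfolded protein and amino acid stress response (0.41); in A/J of acute phase response (0.19), adipose tissue markers (0.25), bile acid synthesis and transport (0.056), biliary and progenitor markers (0.34), fatty acid and triglyceride synthesis (0.19), iron handling (0.19), lipoprotein assembly and clearance (0.13), methionine, folate and choline metabolism (0.19), neutrophil markers (0.21), oxidative stress and glutathione (0.18) and unfolded protein and amino acid stress response (0.21). The counts were 4927 for A/J, 2.8e+02 for C3H/HeJ minus A/J and 3539 called alike. A scaling that adds 1 constant per array moves all genes alike. Here it raised the diet effects by 0.37 in A/J, 0.52 in C3H/HeJ and 0.95 in WSB/EiJ, which by construction turns small falls into rises.

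Normexp correction reversed the sign of Apob (0.13), Mat1a (0.033), Pemt (0.0061) and Slc10a1 (0.051) in A/J; Apob (0.11), Mat1a (0.48), Pemt (0.14) and Slc10a1 (0.084) in C3H/HeJ; Dnmt3b (0.012), Pemt (0.083) and Slc10a1 (0.44) in WSB/EiJ, and the list medians in WSB/EiJ of DNA methylation enzymes (0.24), adipose tissue markers (0.036), iron handling (0.30), oxidative stress and glutathione (0.10) and unfolded protein and amino acid stress response (0.22); in C3H/HeJ of endothelial markers (0.064), fatty acid and triglyceride synthesis (0.24) and iron handling (0.0076); in A/J of iron handling (0.036), lipoprotein assembly and clearance (0.012) and methionine, folate and choline metabolism (0.0061). Quantile normalization reversed the sign of Alb (0.013), Pemt (0.061) and Slc10a1 (0.39) in WSB/EiJ; Apob (0.13), Mat1a (0.057) and Slc10a1 (0.029) in A/J; Apob (0.11), Mat1a (0.40), Pemt (0.0040) and Slc10a1 (0.12) in C3H/HeJ, and the list medians in C3H/HeJ of DNA methylation enzymes (0.0068), endothelial markers (0.10) and fatty acid and triglyceride synthesis (0.21); in WSB/EiJ of DNA methylation enzymes (0.25), iron handling (0.25), oxidative stress and glutathione (0.053) and unfolded protein and amino acid stress response (0.22); in A/J of acute phase response (0.010), iron handling (0.046) and lipoprotein assembly and clearance (0.0065).

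Using only probes above background on all arrays reversed the list medians in A/J of DNA methylation enzymes (-0.023), female-biased liver genes (-0.23) and lymphocyte markers (-0.078); in C3H/HeJ of female-biased liver genes (-0.071) and lymphocyte markers (-0.16); in WSB/EiJ of female-biased liver genes (-1.17) and lymphocyte markers (-0.21). Using 1 array fewer in each group reversed the sign of Cdkn1a (0.53) and Krt19 (0.093) in A/J, and the list medians in WSB/EiJ of DNA methylation enzymes (0.053); in A/J of adipose tissue markers (0.060) and biliary and progenitor markers (0.35); in C3H/HeJ of endothelial markers (0.025) and oxidative stress and glutathione (-0.15). Use of array weights reversed the sign of Cdkn1a (0.25) in A/J, and the list medians in A/J of adipose tissue markers (0.15) and biliary and progenitor markers (0.14); in C3H/HeJ of fatty acid oxidation and ketogenesis (-0.021) and oxidative stress and glutathione (-0.12). Slide as a fixed block reversed the sign of Cdkn1a (0.024) in A/J, and the list medians in A/J of adipose tissue markers (0.14) and biliary and progenitor markers (0.058). Testing without a background filter reversed the list medians in A/J of neutrophil markers (0.42); in WSB/EiJ of neutrophil markers (0.43). Averaging all probes of a gene reversed the sign of Cdkn1a (0.060) in A/J; Hsd17b13 (0.25) in the control diet, C3H/HeJ minus A/J. Median centring reversed the sign of Mat1a (0.040) in C3H/HeJ, and the list medians in C3H/HeJ of endothelial markers (0.031). The deposited table reversed the sign of Mat1a (0.0053) in C3H/HeJ.

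Leaving out each array in turn, with the group of 3 sharing the spread of the others, changed the sign of Cdkn1a in A/J (-0.37 to 0.30); Krt19 in A/J (-0.76 to 0.053); Mat1a in C3H/HeJ (-0.21 to 0.13); the DNA methylation enzymes median in A/J (-0.0018 to 0.045); the adipose tissue markers median in A/J (-0.43 to 0.35); the adipose tissue markers median in WSB/EiJ (-0.81 to 0.018); the biliary and progenitor markers median in A/J (-0.11 to 0.24); the endothelial markers median in C3H/HeJ (-0.081 to 0.073); the fatty acid and triglyceride synthesis median in C3H/HeJ (-0.23 to 0.29); the oxidative stress and glutathione median in C3H/HeJ (-0.095 to 0.13). The counts ranged from 778 to 2182 in A/J, 321 to 1935 for C3H/HeJ minus A/J and 550 to 1671 alike in all 3 strains.

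At an adjusted p of 0.01 the numbers of genes called were 2335 for control-diet C3H/HeJ minus A/J, 4428 for the F test, 617 for A/J, 155 for C3H/HeJ minus A/J, 4960 for C3H/HeJ, 1874 for WSB/EiJ minus C3H/HeJ and 433 called alike. With a log2 change of at least 1 they were 1252 for control-diet C3H/HeJ minus A/J, 2506 for control-diet WSB/EiJ minus A/J, 2237 for control-diet WSB/EiJ minus C3H/HeJ, 533 for A/J, 350 for C3H/HeJ minus A/J, 2283 for C3H/HeJ, 3575 for WSB/EiJ minus A/J, 1737 for WSB/EiJ minus C3H/HeJ, 5107 for WSB/EiJ and 365 called alike, and both settings call fewer by construction. Array weights gave 4036 for A/J, 2219 for C3H/HeJ minus A/J and 3229 called alike, 1 array fewer in each group 4625 for A/J, 899 for C3H/HeJ minus A/J and 3695 called alike, no background filter 332 for C3H/HeJ minus A/J, and only the compared groups in the fit 861 for A/J, 233 for C3H/HeJ minus A/J and 566 called alike. The setting with 1 array fewer replaced a first version that left out the deficient arrays most like the controls, run and withdrawn because it picked arrays by the outcome. The numbers of lists called were 1 for A/J, 2 for C3H/HeJ and 0 for WSB/EiJ by camera with an estimated correlation, and 9 for A/J and 28 for WSB/EiJ by fry, which by construction asks whether a list moves without comparing it with other genes.

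With a replicate block within strain, the numbers of genes called were 794 for A/J, 139 for C3H/HeJ minus A/J and 562 called alike. The numbers do not pair the samples: the array with the same number was the most alike in 1 of 12 cases, and by construction the block removes degrees of freedom. With unchanged fold changes, the calls of Asns, Cyp2c50, Cyp2c54, Fasn, Krt8, Mki67 and Mthfd2 in A/J, Pemt in C3H/HeJ and Cyp4a14, H2-Ab1, H2-Eb1 and Ubd for C3H/HeJ minus A/J ended (adjusted p from 0.0552 to 0.158). Signal over background limits the folds of Gpnmb, H19 and Itgax, given as bounds where no array of a group was above background.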

Other observations

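The test of clock phase and that of unnamed probes were chosen only after results were seen. Among 4626 probes for long intergenic noncoding RNAs, 233 were called in A/J (64 higher on the deficient diet, 169 lower), 1694 in C3H/HeJ (268 and 1426) and 3169 in WSB/EiJ (467 and 2702). Over all unnamed probes the higher and lower ones were 99 and 241 in A/J, 461 and 2269 in C3H/HeJ and 740 and 4300 in WSB/EiJ. These directions were not tested with spike-in scaling, which raised the median of all genes.

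A candidate explanation for the clock genes in A/J is that the diet groups differed in clock phase. On all tested members of the clock list, the mean of the genes with E-box or D-box elements minus that of the genes with RORE elements was higher by 1.96 ± 0.52 (SE, n = 4) on the deficient diet (exact permutation p = 0.0286, 2-sided, the smallest 4 against 4 arrays can give). All 13 E-box or D-box members were higher and 5 of the 5 RORE members lower. RORE members were lower in C3H/HeJ (5 of 5) and WSB/EiJ (5 of 5) too, so that their fall is not particular to A/J, and 5 and 2 of the 13 E-box or D-box members were higher there. The same difference was 0.51 in C3H/HeJ (exact permutation p = 0.143) and -0.22 in WSB/EiJ (exact permutation p = 0.286). Whether the collection times or the diet set the phase was not tested, since the labels give no time of day.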
